A study of Mus musculus with 16 samples.

How the data were processed

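The study measured RNA from the small intestine of mice in 16 samples, 4 per group, in a design crossing Eif3h deletion with the G12D allele of Kras. Per the labels, tamoxifen was injected intraperitoneally 2 times at 80 mg/kg, 24 h apart, and tissue was collected on day 7. RNA was extracted with an RNeasy Micro kit, and libraries made with a TruSeq RNA kit were sequenced as paired ends on a NextSeq instrument. Per the labels, the authors checked reads with FastQC 0.11.8, trimmed them with Trim Galore 0.6.4, aligned them to GRCm38 with HISAT2 2.1.0 and counted them per gene with featureCounts 1.6.4. The annotation release and the strand setting are not stated. The authors deposited raw gene counts, 1 table of whole numbers for 24774 genes and 16 samples. Of these genes, 13 had a blank symbol and held 0.29% to 1.07% of the counts of a library, and 262 had no count in any library. These were kept in the totals.

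Samples were grouped by the genotype in the labels. The replicates are numbered 1 to 4 without further description, so p values describe spread between these samples. Replicate numbers were checked for pairing across groups, and sex labels, given for 14 of 16 samples, matched the expression of sex-linked genes in 14 of 14. Gene positions came from the GRCm38 annotation.

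Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18348. Libraries were scaled by TMM, and the quasi-likelihood model had 1 term per group over all 16 samples. The 5 pairwise comparisons and the interaction, the difference of the deletion effect between both Kras backgrounds, were tested by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. CPM values use the TMM-scaled library sizes. Principal components used log2 CPM with a prior count of 2. The genes Eif3h and Kras were also tested by a two-sided exact permutation test on log2 CPM. The SE of a log2 fold change was its absolute value divided by the square root of the F statistic, so it includes spread between samples. Floors cover counting error only, and where a group had no counts the floor was 3 counts over the group. Library totals of 18071100 to 25391594 counts mean that 1 count corresponds to far less than 1 CPM.

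Before the data were examined, 39 gene lists for cell types, pathways and complexes were fixed, together with the rule for naming genes. Named genes were Eif3h and Kras, the 10 largest rises and 10 largest falls (5 and 5 in the last 3 comparisons) among called genes with at least 2 CPM in the higher group and, for pairwise comparisons, no overlap between groups, and from each list the members with the smallest p. Predicted genes, pseudogenes and symbols of the Rik type were passed over. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, each adjusted over the 39 lists. Fry tests whether a list's genes move on balance one way, without comparing them with other genes. It called 31, 20, 24, 16, 30 and 20 of the lists in Eif3h-deleted against wild type, Kras G12D against wild type, doubly altered against Kras G12D, against Eif3h-deleted and against wild type, and the interaction.

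The effect of sharing the Kras G12D libraries between comparisons was simulated 20 times with groups set unchanged. The procedure was tested on negative binomial counts simulated from the mean of the wild-type libraries and the fitted spread, with 200 genes changed by 1.5-, 2- or 4-fold: for Eif3h-deleted against wild-type samples 31.3%, 67.2% and 97% of them were called, with 6 other calls among 17684 genes, and a planted list was called with 0 of 20 others. For the interaction, 7.5% to 13.4% of 1.5-fold, 38.8% to 55.2% of 2-fold and 89.4% to 92.4% of 4-fold changes were called, over 3 choices of the changed group, so an interaction that was not called can still be present. The simulation changed far fewer genes than the real comparisons, where up to 11983 of 18348 changed. It therefore does not test TMM scaling when most genes change, and its rates need not carry over. The alternatives tried were DESeq2 size factors, total count scaling, other count filters, the DESeq2 1.42.0 Wald test, limma-voom, robust estimation, a test against 1.5-fold, only the groups compared, a replicate block, sex as a covariate, removal of the 20 most abundant genes and leaving out each library. Alternatives chosen after seeing the data left out libraries with adipocyte transcripts or with little smooth muscle signal, or took scaling factors from abundant genes outside the lists.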

Results

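RNA from mouse small intestine was sequenced in 16 samples, which formed 4 groups of 4 replicates. The groups were wild type, mice with Eif3h deleted, mice with the G12D allele of Kras, and mice with both alterations. Eif3h encodes a subunit of the translation initiation factor eIF3, and Kras encodes a GTPase upstream of the MAPK cascade. The labels name VilCreER, a tamoxifen-activated recombinase expressed from the villin promoter in intestinal epithelium, in the 3 altered groups. They do not say whether the wild-type mice carried it, or whether the whole wall or the separated epithelium was taken. Each altered group can therefore differ from wild type in the recombinase as well. Total counts per sample ran from 18071100 to 25391594. The group means were 22541263 ± 1081612 in wild-type, 21323803 ± 2355893 in Eif3h-deleted, 22838822 ± 1211102 in Kras G12D and 22499466 ± 2720595 in doubly altered samples (SD, n = 4 each). Expression is given below as CPM, counts scaled to the library size, mean ± SD of 4 samples, and log2 fold changes are given ± SE.

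The Eif3h transcript (chromosome 15, 51786558 to 51865523, minus strand, GRCm38) fell in both deleted groups. It measured 117.5 ± 3.5 CPM in wild-type and 21.0 ± 1.7 CPM in Eif3h-deleted samples, 17.9% of the wild-type level, with a log2 fold change of -2.48 ± 0.09 (adjusted p = 2.68e-10). With Kras G12D it measured 135.9 ± 6.6 CPM when Eif3h was intact and 31.2 ± 3.8 CPM when it was deleted, 23.0% of the intact level (log2 fold change -2.12 ± 0.09, adjusted p = 4.39e-10). The residual Eif3h signal was 0.57 ± 0.09 higher on the log2 scale in doubly altered than in Eif3h-deleted samples (adjusted p = 0.000356). The Kras transcript (chromosome 6, 145216699 to 145250239, minus strand) measured 79.2 ± 7.2 CPM in wild-type, 101.1 ± 2.8 in Eif3h-deleted, 113.3 ± 7.9 in Kras G12D and 119.0 ± 4.7 in doubly altered samples. It was higher in Kras G12D than in wild-type samples by 0.52 ± 0.07 (adjusted p = 0.000352). Between doubly altered and Kras G12D samples it differed by 0.07 ± 0.07, which did not pass (adjusted p = 0.437). A two-sided exact permutation test gave p = 0.0286, the smallest that 4 against 4 samples allow, for each of these differences except the last, where exact p = 0.2571. Gene counts do not show the deleted exons or the altered base themselves.

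**Figure D1:**
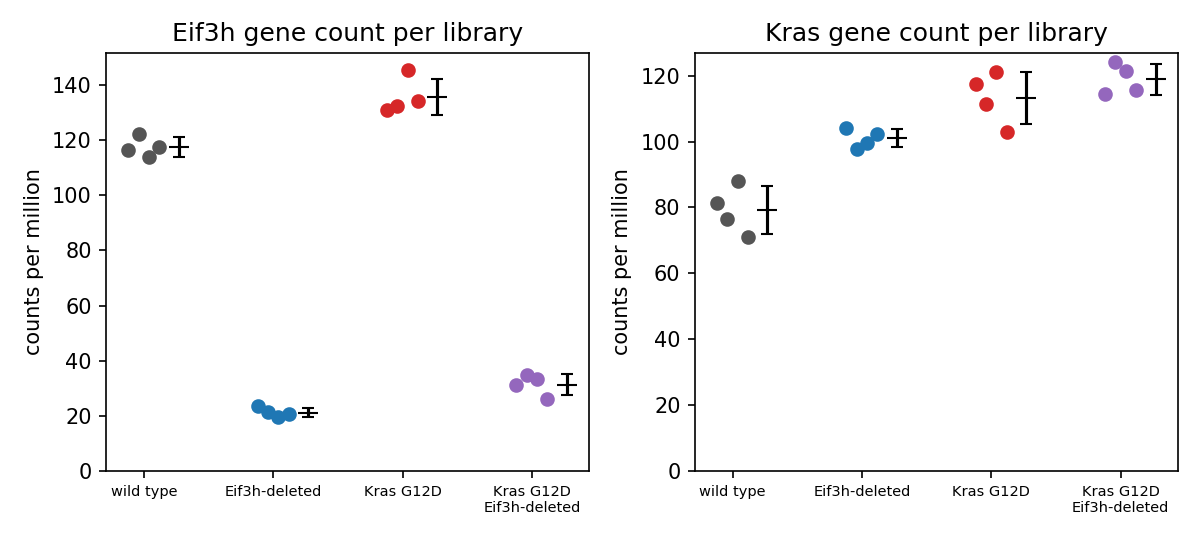
Normalised counts of the Eif3h and Kras genes (CPM, linear axis from 0) in each of the 16 libraries, with the group mean and SD beside the 4 points of each group. Eif3h measured 117.5 and 135.9 CPM on average in the intact groups and 21.0 and 31.2 CPM in the deleted groups.

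The first principal component held 54.5% of the variance and separated the 8 samples with Eif3h deleted from the 8 without. The second held 12.5%. Of 18348 genes tested, 11486 changed in Eif3h-deleted against wild-type samples, 5233 in Kras G12D against wild type, 9788 in doubly altered against Kras G12D, 4338 in doubly altered against Eif3h-deleted, and 11983 in doubly altered against wild type. Expression was also summarised over 39 gene lists fixed before the data were examined. Camera with a preset correlation called 21, 23, 20, 21 and 24 of the lists in these comparisons, and 2, 0, 0, 3 and 3 with an estimated correlation (7, 4, 11, 6 and 11 at an unadjusted p under 0.05). Each list below is therefore given with both adjusted p values. Counts of members adjusted over the list alone are given where they differ from the counts over all genes and are otherwise the same.

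**Figure D2:**
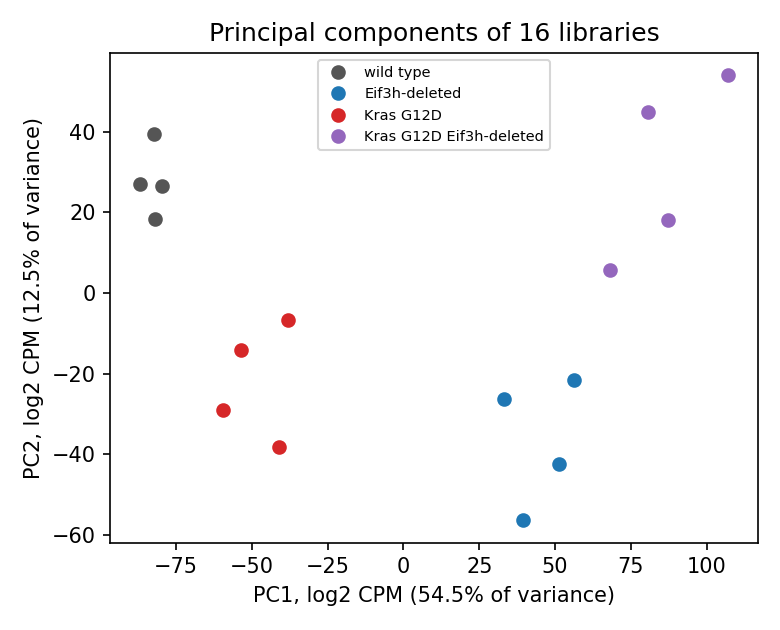
Principal components 1 and 2 of log2 CPM, 1 point per library coloured by group, with the percent of variance on each axis. The 8 libraries with Eif3h deleted lie at PC1 scores from 33.02 to 107.01 and the 8 others from -86.86 to -38.04.

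Deletion of Eif3h on the wild-type Kras background addresses what loss of this subunit does in otherwise unaltered intestine. Transcripts for protein synthesis rose: 78 of 79 ribosomal protein genes were higher, with a median log2 fold change of 1.19, and Rplp0, a protein of the ribosomal stalk, went from 482.4 ± 17.7 CPM in wild-type to 1606 ± 71.8 CPM in deleted samples. Markers of secretory lineages fell: 14 of 14 tuft cell, 12 of 19 enteroendocrine and 10 of 16 goblet cell genes were lower. Genes of the amino acid response and of sterol synthesis rose, with Asns, which makes asparagine, going from 19.5 to 129 CPM. In all, 5346 genes rose and 6140 fell, and 1786 rose and 3267 fell by more than 2-fold.

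Ribosomal protein genes were called higher by camera (adjusted p = 4.35e-45, and adjusted p = 0.113 with an estimated correlation). All 24 genes of ribosome assembly and MYC rose, with a median of 1.27 (adjusted p = 4.58e-21, and adjusted p = 0.113 with an estimated correlation). Among them Srm, spermidine synthase, rose by 2.44 ± 0.15 (adjusted p = 5.4e-09) and the ribosome assembly factor Rrp12 by 1.69 ± 0.10 (adjusted p = 4.04e-09). The other 13 subunits of eIF3 all rose, with a median of 0.76 (adjusted p = 5.56e-08, and adjusted p = 0.113 with an estimated correlation), among them Eif3a by 1.06 ± 0.09 (adjusted p = 9.15e-08). Of 28 initiation factors outside eIF3, 23 rose and 1 fell, with 24 and 1 adjusted over the list alone (median 0.86, adjusted p = 9.81e-13, and adjusted p = 0.0266 with an estimated correlation). Eif4ebp1, a repressor of cap-dependent initiation, was the member with the smallest p and rose from 13.8 to 99.3 CPM.

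Of 28 targets of ATF4 and the amino acid response, 21 rose and 3 fell, with 22 and 3 adjusted over the list alone (median 1.14, adjusted p = 1.27e-14, and adjusted p = 0.0109 with an estimated correlation). Atf5, a stress-induced transcription factor, rose from 15.2 to 160 CPM, and Gars, the glycyl-tRNA synthetase, from 75.5 to 319 CPM. Sterol synthesis genes rose in 17 of 22 cases and fell in 3 (median 1.48, adjusted p = 8.22e-07, and adjusted p = 0.504 with an estimated correlation), with Pcsk9, which degrades the LDL receptor, 3.19 ± 0.15 higher (adjusted p = 8.17e-10). Of 12 genes for EGF family ligands and receptors, 7 rose and 4 fell (median 1.31, adjusted p = 0.00434, and adjusted p = 0.124 with an estimated correlation). The EGF receptor ligand Areg went from 10.3 to 177 CPM. MAPK output genes rose in 13 of 20 cases and fell in 2 (median 0.98, adjusted p = 0.00082, and adjusted p = 0.406 with an estimated correlation), led by the transcription factor Etv4, which went from 1.05 to 14.9 CPM. YAP and fetal-like genes rose in 9 of 19 cases and fell in 3 (median 0.97, adjusted p = 0.00667, and adjusted p = 0.537 with an estimated correlation). Cell cycle genes rose in 25 of 35 cases, 26 adjusted over the list alone (median 0.60, adjusted p = 0.000125, and adjusted p = 0.601 with an estimated correlation). Of the 13 protein-coding transcripts of the mitochondrial genome, 12 fell (median -0.49, adjusted p = 0.00171, and adjusted p = 0.504 with an estimated correlation).

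Tuft cell markers fell with a median of -2.54 (adjusted p = 1.02e-06, and adjusted p = 0.114 with an estimated correlation), among them the taste-signalling channel Trpm5, from 16.9 to 1.61 CPM, and the tuft marker Dclk1, from 17.3 to 2.99 CPM. Enteroendocrine markers fell with a median of -1.50 (adjusted p = 0.00434, and adjusted p = 0.502 with an estimated correlation). They included the hormone genes Gcg (-2.71 ± 0.27, adjusted p = 6.3e-07), Sst (-2.03 ± 0.20, adjusted p = 7.05e-07) and Gip (-2.25 ± 0.29, adjusted p = 8.75e-06). Goblet cell markers had a median of -0.75, with 1 member higher (adjusted p = 0.0112, and adjusted p = 0.54 with an estimated correlation). Paneth cell markers fell in 14 of 20 cases (median -1.74, adjusted p = 0.0401, and adjusted p = 0.69 with an estimated correlation). That call was lost without wild-type replicates 1 (0.0878) or 2 (0.0852), Eif3h-deleted replicates 3 (0.0636) or 4 (0.0555), or both wild-type replicates 1 and 4 (0.129), and with all 16 samples under total count scaling (0.0539) or scaling from genes outside the lists (0.0635), in a range from 0.00038 to 0.69 over 26 alternatives. Enterocyte genes went both ways, 7 higher and 10 lower of 31 (adjusted p = 0.76, and adjusted p = 0.94 with an estimated correlation): Treh, which digests trehalose, fell from 547 to 23 CPM, and the surface keratin Krt20 rose from 2148 to 5671 CPM. Among named genes, which had no overlap between groups and at least 2 CPM in the higher group, the falls included Dio1, a deiodinase that activates thyroid hormone, from 123.4 ± 30.1 to 0.363 ± 0.203 CPM, and Cyp2b10, a drug-metabolising cytochrome, from 312.4 ± 44.1 to 0.348 ± 0.331 CPM. Gsdmc2, of the gasdermin family, had 579 counts in wild-type samples and 0 in deleted ones, at least 177.5-fold lower against a floor of 3 counts per group. Reads of the close Gsdmc paralogs can be shared, so this gene's identity within the family is uncertain. The rises included Syt8, of the synaptotagmin family, at 0.0116 ± 0.0232 CPM in wild-type and 62.1 ± 37.2 CPM in deleted samples, and the annexin Anxa10, at 0.0192 ± 0.0385 and 62.5 ± 57.4 CPM.

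Markers of other cell types were lower as well. Of 11 enteric neuron and glia markers 10 fell (median -1.61, adjusted p = 0.0149, and adjusted p = 0.601 with an estimated correlation), and of 15 T cell markers 12 fell (median -1.99, adjusted p = 0.0112, and adjusted p = 0.676 with an estimated correlation). Fibroblast markers fell in 9 of 13 cases (median -0.78, adjusted p = 0.0187, and adjusted p = 0.601 with an estimated correlation). Smooth muscle markers fell in 11 of 12 cases (median -1.47, adjusted p = 0.0293, and adjusted p = 0.685 with an estimated correlation). That last call was lost without wild-type replicate 2 (adjusted p = 0.0574) or Eif3h-deleted replicate 4 (adjusted p = 0.0643), the latter being a library with little smooth muscle signal, in a range from 0.00301 to 0.685 over 26 alternatives. Adipocyte transcripts stood out in wild-type replicates 1 and 4, where Cfd, an adipocyte protease, reached 17.6 and 162.3 CPM against 0.2 and 0 CPM in wild-type replicates 2 and 3. Eif3h-deleted replicate 1 carried some of this signal, with Cfd at 8.2 CPM.

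Kras G12D with Eif3h intact addresses what the activated allele does alone within the days after induction. Sterol synthesis and glycolysis genes rose: 19 of 22 and 13 of 18 members were higher, with medians of 1.09 and 0.76. Paneth cell markers fell in 20 of 20 cases, with a median of -2.76, and the antimicrobial peptide gene Defa24 went from 1276 to 174.0 CPM. The MAPK-responsive transcription factor Etv4 rose from 1.05 ± 0.309 to 15.6 ± 2.27 CPM. In all, 2867 genes rose and 2366 fell, 424 and 1102 of them by more than 2-fold.

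Sterol synthesis was called higher (adjusted p = 7.55e-16, and adjusted p = 0.299 with an estimated correlation), 22 of its 22 members rising when adjusted over the list alone. Glycolysis was called higher (adjusted p = 1.96e-10, and adjusted p = 0.153 with an estimated correlation), with 1 member lower and 14 higher when adjusted over the list alone. The rate-limiting glycolytic enzyme Pfkl rose by 1.67 ± 0.13 (adjusted p = 3.58e-06) and Aldoa, an aldolase, by 1.06 ± 0.12 (adjusted p = 8.66e-05). MAPK output genes rose in 6 of 20 cases and fell in 2 (median 0.25, adjusted p = 0.00294, and adjusted p = 0.385 with an estimated correlation). Dusp4, a MAPK phosphatase, was 1.20 ± 0.16 higher (adjusted p = 0.000232). NRF2 antioxidant genes rose in 8 of 18 cases and fell in 1, with 9 and 1 adjusted over the list alone (median 0.50, adjusted p = 0.00153, and adjusted p = 0.353 with an estimated correlation). Ribosomal protein genes rose in 24 of 79 cases, or 37 adjusted over the list alone, with a median of 0.25, or 0.12 with total count scaling and 0.13 with scaling from genes outside the lists (adjusted p = 2.2e-06, and adjusted p = 0.552 with an estimated correlation).

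Paneth cell markers had camera adjusted p = 3.5e-14, and adjusted p = 0.299 with an estimated correlation. The defensin genes are close paralogs, so reads can be shared among them. Crypt stem cell markers fell in 10 of 18 cases (median -0.42, adjusted p = 2.09e-05, and adjusted p = 0.299 with an estimated correlation), among them Ascl2, a transcription factor of stem cells, by 1.72 ± 0.29 on the log2 scale (adjusted p = 0.000874). Wnt targets fell in 8 of 19 cases and rose in 1 (median -0.51, adjusted p = 0.000526, and adjusted p = 0.299 with an estimated correlation), including Axin2, a feedback regulator of the pathway, from 61.8 to 31.7 CPM. Lgr5, Ascl2, Sox9, Rnf43, Znrf3 and Tnfrsf19 are in both the stem cell and the Wnt list, so both results rest partly on the same genes. Enteroendocrine markers fell in 8 of 19 cases, or 9 with 1 higher adjusted over the list alone (median -0.55, adjusted p = 0.00161, and adjusted p = 0.353 with an estimated correlation). Tuft cell markers fell in 6 of 14 cases, or 8 adjusted over the list alone (median -0.76, adjusted p = 0.000654, and adjusted p = 0.299 with an estimated correlation). Large rises included Tcf23, a bHLH transcription factor, from 2.35 ± 0.521 to 44.8 ± 4.42 CPM, and Slc27a6, a fatty acid transport protein, from 0.433 ± 0.156 to 10.9 ± 1.52 CPM. Slc5a12, a lactate transporter, was among the large falls, from 108.0 ± 40.5 to 6.99 ± 4.42 CPM.

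Enteric neuron and glia markers were lower in 8 of 11 cases, 11 adjusted over the list alone (median -1.36, adjusted p = 1.66e-06, and adjusted p = 0.299 with an estimated correlation). Other non-epithelial and immune markers were also called lower. The medians were -0.82 for smooth muscle (2 of 12 members, or 0 adjusted over the list alone, adjusted p = 0.00661), -0.78 for myeloid cells (4 of 14, or 9 adjusted over the list alone, adjusted p = 0.00434), -0.62 for fibroblasts (3 of 13, adjusted p = 0.00398) and -0.47 for endothelium (2 of 11, adjusted p = 0.00799). They were -1.12 for MHC class II (4 of 8, or 6 adjusted over the list alone, adjusted p = 0.00799) and -0.71 for T cells, where edgeR called 0 of 15 members and 2 were lower at an unadjusted p under 0.05 (adjusted p = 0.0385). With an estimated correlation the adjusted p of these 6 lists ran from 0.525 to 0.67. Calls were lost for smooth muscle without Kras G12D replicate 2 (adjusted p = 0.119), for endothelium without wild-type replicate 4 (0.0712), for MHC class II without wild-type replicate 3 (0.0779) or Kras G12D replicate 4 (0.0565), and for T cells without wild-type replicates 3 (0.275) or 4 (0.128), Kras G12D replicate 4 (0.282) or doubly altered replicate 1 (0.057). With all 16 samples the T cell call was lost under total count scaling (0.114) or scaling from genes outside the lists (0.126). Over the 14 samples with a sex label the smooth muscle call was lost (0.0777), and with sex as a covariate the fibroblast call (0.0538). Without wild-type replicates 1 and 4, the libraries with adipocyte transcripts, 4 of the 6 calls were lost: myeloid cells (0.155), fibroblasts (0.252), endothelium (0.536) and T cells (0.198). The Kras G12D group includes replicate 2, another library with little smooth muscle signal. Cyp2e1, an alcohol-metabolising cytochrome, fell by 7.40 ± 1.65 on the log2 scale (adjusted p = 0.00664). Its wild-type values were 7.3, 0.6, 1.1 and 48.5 CPM, the high ones in the libraries with adipocyte transcripts, and without those libraries the log2 fold change was -3.36 ± 1.15 (adjusted p = 0.0847). The call was also lost with limma-voom (adjusted p = 0.0772) and over the 14 samples with a sex label (adjusted p = 0.0862, and adjusted p = 0.128 with sex as a covariate), in a range from 0.000111 to 0.128 over 32 alternatives. The count of changed genes was 2145 without those libraries and 1697 over the 14 samples with a sex label, which drop Kras G12D replicates 2 and 3. Scaling by total counts moved the median of all genes from 0.04 to -0.09 and the share of called genes that were higher from 54.8% to 30.1%, so the balance of rises and falls in this comparison depends on the scaling.

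Deletion of Eif3h on the Kras G12D background addresses what the loss does in intestine carrying the activated allele. All 79 ribosomal protein genes rose, with a median of 1.13, while 18 of 19 enteroendocrine and 14 of 16 goblet cell markers fell, with medians of -3.37 and -2.99. A group of YAP targets and fetal or regenerative markers rose in 15 of 19 cases, with a median of 3.40, and Krt7, a keratin of simple epithelia, went from 93.6 to 987 CPM. All 13 mitochondrial transcripts and 33 of 36 nuclear genes of the respiratory chain and ATP synthase fell. In all, 4670 genes rose and 5118 fell, 1754 and 2251 of them by more than 2-fold.

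Enteroendocrine markers had adjusted p = 2.13e-13, and adjusted p = 0.0526 with an estimated correlation. The incretin gene Gip fell from 47.4 to 1.12 CPM and Gcg from 10.6 to 0.26 CPM. Goblet cell markers had adjusted p = 5.71e-14, and adjusted p = 0.0604 with an estimated correlation. Their members included Spink4, a secreted protease inhibitor, which fell from 187 to 20.6 CPM, and Creb3l1, a transcription factor of secretory cells, which fell by 2.38 ± 0.11 (adjusted p = 7.3e-10). Tuft cell markers fell in 9 of 14 cases and rose in 1 (median -1.68, adjusted p = 0.0165, and adjusted p = 0.432 with an estimated correlation). Paneth cell markers fell in 13 of 20 cases and rose in 1, with 16 and 2 adjusted over the list alone (adjusted p = 0.0141, and adjusted p = 0.8 with an estimated correlation). Their median was -2.68, or -2.55 with the member that had no counts set at its bound. The stem cell marker Olfm4 fell from 402 to 2.68 CPM, although stem cell markers as a list were not called, with 5 higher and 10 lower of 18, and 5 and 11 adjusted over the list alone (adjusted p = 0.624).

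The YAP and fetal-like list had adjusted p = 3.11e-10, and adjusted p = 0.0604 with an estimated correlation. The calcium-binding protein gene S100a6 rose from 95.3 to 1571 CPM and the ligand Ereg from 2.11 to 33.2 CPM. Of 12 genes for EGF family ligands and receptors 7 rose and 2 fell, with 7 and 3 adjusted over the list alone (median 0.97, adjusted p = 0.000882, and adjusted p = 0.0604 with an estimated correlation). The receptor gene Egfr rose from 33.0 to 196 CPM. MAPK output genes rose in 12 of 20 cases (median 0.73, adjusted p = 0.00178, and adjusted p = 0.357 with an estimated correlation). Targets of ATF4 and the amino acid response rose in 19 of 28 cases and fell in 4 (median 0.65, adjusted p = 1.46e-07, and adjusted p = 0.0526 with an estimated correlation).

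Ribosomal protein genes had adjusted p = 2.86e-44, and adjusted p = 0.0604 with an estimated correlation. Ribosome assembly and MYC genes rose in 22 of 24 cases (median 0.74, adjusted p = 1.17e-09, and adjusted p = 0.234 with an estimated correlation), and 12 of the 13 other eIF3 subunits rose (median 0.50, adjusted p = 0.000185, and adjusted p = 0.164 with an estimated correlation). Respiratory chain genes had a median of -0.54, with 36 of 36 lower when adjusted over the list alone (adjusted p = 8.41e-09, and adjusted p = 0.432 with an estimated correlation). Mitochondrial transcripts had a median of -1.01 (adjusted p = 6.94e-09, and adjusted p = 0.119 with an estimated correlation). All genes of the mitochondrial genome together, not only the list, held 4.35% to 4.92% of the counts with a gene symbol in the Kras G12D libraries. In the doubly altered ones they held 2.26% to 2.52%. Fatty acid oxidation genes fell in 14 of 21 cases and rose in 2 (median -0.98, adjusted p = 2.44e-05, and adjusted p = 0.175 with an estimated correlation), with Acaa2, a mitochondrial thiolase, 2.00 ± 0.17 lower (adjusted p = 1.63e-07). Markers of the duodenal end of the small intestine fell in 6 of 11 cases (median -2.63, adjusted p = 0.000554, and adjusted p = 0.0604 with an estimated correlation). Large falls included Abcc6, an efflux transporter, from 61.2 ± 10.4 to 0.241 ± 0.257 CPM, and Rdh7, a retinol dehydrogenase with close paralogs, from 198.5 ± 57.1 to 1.04 ± 0.626 CPM. Zyg11a, of a ubiquitin ligase adaptor family, had 326 counts in Kras G12D and 0 in doubly altered samples, at least 108.3-fold lower. Large rises included Wfdc2, a secreted protease inhibitor, from 0.168 ± 0.101 to 71.9 ± 23.2 CPM, and the desmosomal cadherin Dsg3, from 0.0587 ± 0.0621 to 27.4 ± 16 CPM.

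Myeloid markers rose in 11 of 14 cases, 12 adjusted over the list alone (median 0.83, adjusted p = 0.0233, and adjusted p = 0.8 with an estimated correlation). That call was lost without doubly altered replicate 2 (adjusted p = 0.0526, in a range from 0.00602 to 0.8 over 26 alternatives).

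**Figure D3:**
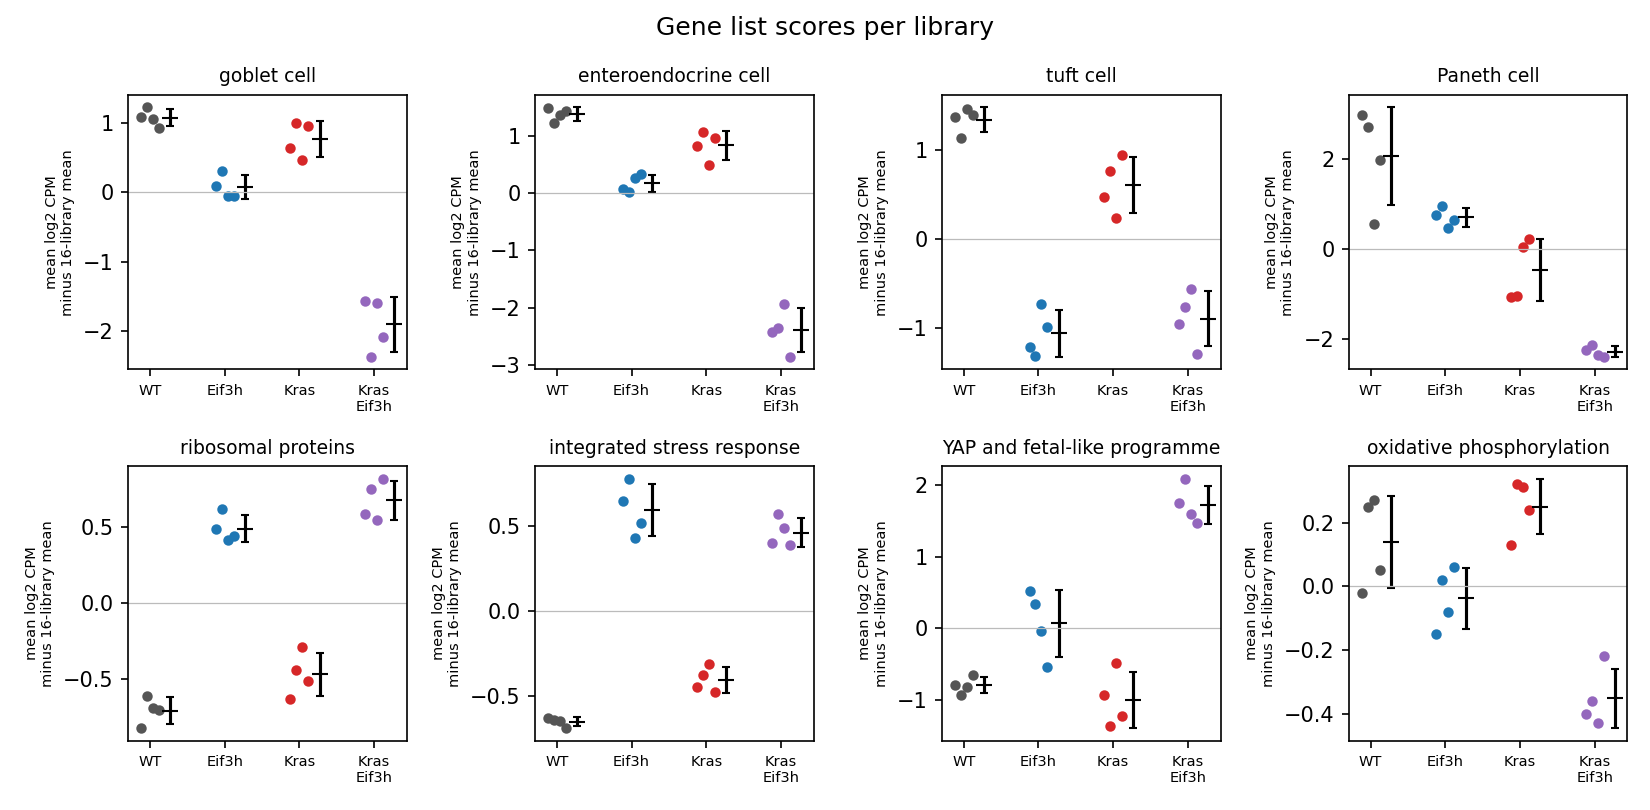
Scores of 8 gene lists in each of the 16 libraries: the mean over the list of log2 CPM after subtracting each gene's mean over all libraries, with the group mean and SD beside the points. Members of the enteroendocrine list fell in 18 of 19 cases and those of the goblet list in 14 of 16 cases between Kras G12D and doubly altered samples.

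The interaction asked whether the effect of Eif3h deletion differed between the 2 Kras backgrounds. If the wild-type mice lacked VilCreER, the deletion effect without Kras G12D includes the recombinase, and that with Kras G12D does not. The interaction cannot tell such a difference from a dependence on Kras G12D. The fall differed for markers of some secretory lineages: goblet cell markers fell by a median of 2.12 more on the log2 scale with Kras G12D than without, and enteroendocrine markers by 2.35 more. The goblet cell regulator Atoh1 measured 11.1 and 9.23 CPM in wild-type and Eif3h-deleted samples, and 8.45 and 0.964 CPM in Kras G12D and doubly altered ones. Of 19 YAP and fetal-like genes, 7 had a higher effect of the deletion with Kras G12D, and 9 rose and 3 fell after deletion on the wild-type background. Among them Clu measured 23.1, 11.8, 14.6 and 158 CPM in the same order. Camera called 23 of 39 lists with the preset correlation and 0 with an estimated one (5 at an unadjusted p under 0.05), and fry 20. In all, 4863 genes passed, 2230 with a higher and 2633 with a lower effect of the deletion on the Kras G12D background.

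Of the goblet list 12 members had a lower and 2 a higher effect, with 13 and 2 adjusted over the list alone (adjusted p = 9.5e-13, and adjusted p = 0.126 with an estimated correlation). Of 19 enteroendocrine genes 14 had a lower effect, 16 adjusted over the list alone (adjusted p = 1.99e-12, and adjusted p = 0.102 with an estimated correlation). The mucus protein disulfide isomerase Agr2 had a difference of -3.76 ± 0.38 (adjusted p = 2.53e-05) and the endocrine transcription factor Neurod1 of -2.89 ± 0.36 (adjusted p = 0.000117). Paneth cell markers were not called, with 1 member higher and 1 lower of 20, and 0 and 0 adjusted over the list alone (median -0.93, adjusted p = 0.258, and adjusted p = 0.805 with an estimated correlation). At an unadjusted p under 0.05, 1 was higher and 4 were lower. Tuft cell markers differed in the opposite direction, with 7 of 14 higher, 8 adjusted over the list alone (median 0.90, adjusted p = 0.00272, and adjusted p = 0.381 with an estimated correlation). YAP and fetal-like genes had a higher effect in 7 of 19 cases, 9 adjusted over the list alone (median 0.67, adjusted p = 5.92e-06, and adjusted p = 0.316 with an estimated correlation). Among them the cell surface protein Msln differed by 7.55 ± 1.12 (adjusted p = 0.000374) and Anxa1, an annexin, by 3.57 ± 0.47 (adjusted p = 0.000161). Sterol synthesis genes had a lower effect in 15 of 22 cases, 19 adjusted over the list alone (median -1.04, adjusted p = 2.99e-09, and adjusted p = 0.381 with an estimated correlation). Respiratory chain genes had a lower effect in 22 of 36 cases, 25 adjusted over the list alone (median -0.44, adjusted p = 7.81e-08, and adjusted p = 0.403 with an estimated correlation). Ribosome assembly genes had a lower effect in 14 of 24 cases, 19 adjusted over the list alone (median -0.53, adjusted p = 8.51e-06, and adjusted p = 0.403 with an estimated correlation). Ribosomal protein genes differed in 1 of 79 cases, or 5 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median -0.05, which became 0.01 with total count scaling; adjusted p = 0.604). MHC class II genes had a higher effect in 7 of 8 cases, 8 adjusted over the list alone (median 2.34, adjusted p = 2.05e-05, and adjusted p = 0.381 with an estimated correlation). T cell markers had a higher effect in 7 of 15 cases, 10 adjusted over the list alone (median 2.00, adjusted p = 4.94e-05, and adjusted p = 0.403 with an estimated correlation). The share of called genes with a higher effect was 45.9%, and 59.7% when scaling factors came from abundant genes outside the lists.

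Across the 18348 genes, the effects of the deletion on both backgrounds correlated with Pearson r = 0.65 and Spearman rho = 0.62. This correlation is across genes, which are not independent replicates, and the comparisons share no library. Of the called genes, 3241 rose and 3427 fell on both backgrounds, where the sizes of the sets alone would give 1361 and 1713. Another 197 rose without and fell with Kras G12D, and 236 fell without and rose with it, where 1491 and 1563 would be given by the sizes alone.

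**Figure D4:**
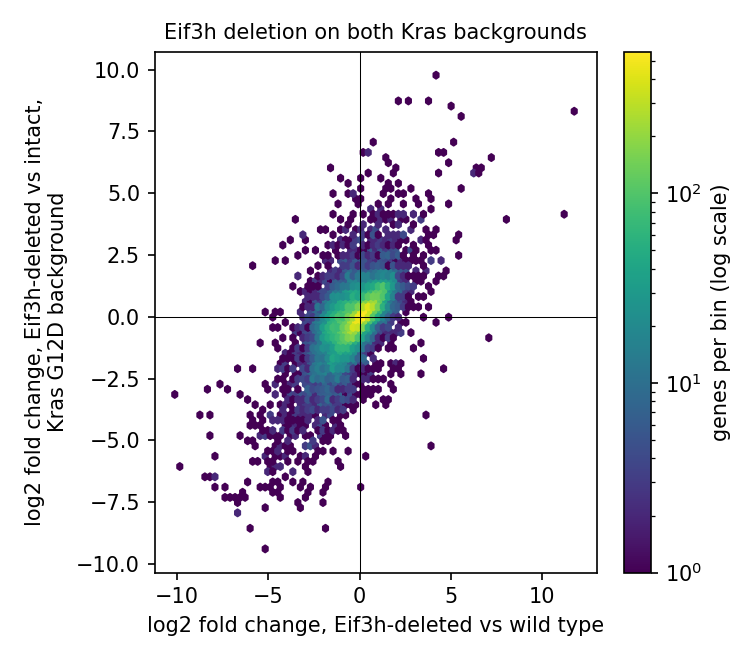
Log2 fold change after Eif3h deletion in Eif3h-deleted against wild-type samples (horizontal) and in doubly altered against Kras G12D samples (vertical), with colour giving the number of genes per hexagon on a log scale. The 18348 tested genes spread along the diagonal with Pearson r = 0.65 across genes.

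The design also asks how genes changed by Kras G12D respond when Eif3h is lost. Of the 5233 genes changed by Kras G12D, 42.5% had the opposite sign in doubly altered against Kras G12D samples. The 2867 raised genes had a median of 0.08 there, with 1035 rising further and 858 falling, and the 2366 lowered genes had a median of -0.18, with 610 falling further and 389 rising. Neither median exceeded its jackknife SE of 0.096 and 0.202, and leaving out 1 library gave 0.06 to 0.13 and, from without wild-type replicate 4 to without Kras G12D replicate 3, -0.25 to -0.05. Both comparisons use the Kras G12D libraries with opposite sign, which by itself produces apparent reversal. In data simulated with no difference between doubly altered and Kras G12D samples, 62.1% had the opposite sign, with a range of 60.5% to 63.6% over 20 simulations. With the Kras G12D libraries split 2 and 2 between the comparisons, the share was 33.8% to 47.2%. Across all genes the correlation of the comparisons was 0.05, and -0.02 to 0.19 with the Kras G12D libraries split. In simulations it was -0.5 with all groups unchanged, and -0.2 (range -0.23 to -0.18) with only doubly altered and Kras G12D samples equal. These correlations cannot be set directly against the real one, because the simulated data lack some or all of the real changes. The covariance was 0.041, where -0.049 and -0.047 were simulated.

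Doubly altered against Eif3h-deleted samples addresses what Kras G12D adds once Eif3h is lost. Markers of 3 secretory lineages were lower with Kras G12D: enteroendocrine genes fell in 17 of 19 cases, goblet cell genes in 13 of 16, and Paneth cell genes in 17 of 20. YAP and fetal-like genes rose in 12 of 19 cases, with a median of 1.13. The stem cell marker Olfm4 fell from 72.1 ± 40.0 to 2.68 ± 2.39 CPM. In all, 2265 genes rose and 2073 fell.

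Enteroendocrine markers had a median of -3.08 and goblet cell markers of -2.62, with 1 goblet gene higher. Both calls held with an estimated correlation (adjusted p = 4.59e-34 and 3.41e-30 with the preset, and adjusted p = 0.00102 and 0.00525 with an estimated correlation). Paneth cell markers had a median of -3.94, or -3.78 with the member that had no counts set at its bound, and 18 members fell adjusted over the list alone (adjusted p = 1.43e-17, and adjusted p = 0.137 with an estimated correlation). YAP and fetal-like genes had adjusted p = 1.46e-09, and adjusted p = 0.109 with an estimated correlation. Respiratory chain genes fell in 23 of 36 cases, 27 adjusted over the list alone (median -0.32, adjusted p = 1.67e-09, and adjusted p = 0.52 with an estimated correlation). Mitochondrial transcripts fell in 11 of 13 cases, 12 adjusted over the list alone (median -0.40, adjusted p = 5.74e-06, and 0.351). Of 14 exocrine pancreas markers only 3 were measured, and 2 of them fell (median -2.74, adjusted p = 0.000369, and 0.0251). Zg16, among these 3, is also in the goblet cell list, so this call is not separate from the goblet fall. Cytokine and chemokine genes rose in 9 of 13 cases and fell in 2, with 10 and 2 adjusted over the list alone (median 1.56, adjusted p = 0.0156, and adjusted p = 0.558 with an estimated correlation). Markers of immune cells rose with them: T cell markers in 5 of 15 cases, or 6 adjusted over the list alone (median 1.25, adjusted p = 0.000851, and adjusted p = 0.588 with an estimated correlation), MHC class II in 6 of 8, or 8 (median 1.16, adjusted p = 0.00172, and 0.52), and myeloid markers in 6 of 14, or 8 (median 0.63, adjusted p = 0.00262, and 0.588). The rise of cytokine and of myeloid genes was not seen in doubly altered replicate 4. Cytokine scores were 0.64, 1.96, 1.02 and -0.23 in doubly altered replicates 1 to 4, against -0.58 to -0.18 in Eif3h-deleted libraries. Myeloid scores were 0.81, 1.42, 0.8 and -0.22, against -0.52 to 0.26. T cell and MHC class II scores of the doubly altered libraries all lay above those of the Eif3h-deleted ones. T cell markers had been low in Eif3h-deleted samples, with a median of -1.99 against wild type. In doubly altered against Kras G12D samples their median was 0.03, with 0 of 15 called. Against wild type the doubly altered medians were -0.69 for T cells, -0.50 for MHC class II and 0.19 for myeloid markers, none of which camera called. B and plasma cell markers rose in 3 of 13 cases, or 5 adjusted over the list alone (median 1.11, adjusted p = 0.044, and adjusted p = 0.767 with an estimated correlation), a call lost without Eif3h-deleted replicates 2 (0.0672) or 3 (0.0544) or doubly altered replicates 3 (0.266) or 4 (0.0892), or without the 20 most abundant genes (0.051). The share of called genes that were higher was 52.2%, and 38.6% with total count scaling. Leaving out Kras G12D replicate 2 and Eif3h-deleted replicate 4 gave 2861 changed genes in place of 4338.

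Both alterations together against neither left 5785 genes higher and 6198 lower. All 19 enteroendocrine and 15 of 16 goblet cell markers fell, with medians of -3.67 and -3.29, and 18 of 20 Paneth cell markers fell. Ribosomal protein genes rose in 78 of 79 cases, or 79 adjusted over the list alone, with a median of 1.38. MAPK output genes rose in 15 of 20 cases and fell in 1, with 16 and 1 adjusted over the list alone and a median of 1.32. Psca, a surface antigen, had 0 counts in wild-type and 695 in doubly altered samples, at least 251.9-fold higher.

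Enteroendocrine markers had adjusted p = 6.57e-14, and adjusted p = 0.0289 with an estimated correlation. Goblet cell markers had adjusted p = 3.58e-13, and adjusted p = 0.056 with an estimated correlation. Paneth cell markers had a median of -5.77, or -5.49 with the member that had no counts set at its bound (adjusted p = 8.19e-07, and adjusted p = 0.359 with an estimated correlation). Ribosomal protein genes had adjusted p = 2.71e-46, and adjusted p = 0.0885 with an estimated correlation. MAPK output genes had adjusted p = 2.55e-05, and adjusted p = 0.167 with an estimated correlation. Targets of ATF4 and the amino acid response rose in 20 of 28 cases and fell in 6 (median 1.55, adjusted p = 5.62e-09, and adjusted p = 0.0289 with an estimated correlation). Enteric neuron and glia markers fell in 10 of 11 cases, 11 adjusted over the list alone (median -1.88, adjusted p = 0.00736, and 0.49). Fibroblast markers fell in 8 of 13 cases (median -0.77, adjusted p = 0.0211, and 0.52). Markers of the duodenal end fell in 7 of 11 cases and rose in 2 (median -1.90, adjusted p = 0.0174, and 0.172). All 13 mitochondrial transcripts fell (median -0.92, adjusted p = 4.8e-07, and 0.166). Total count scaling moved the median of all genes from -0.04 to -0.15 in this comparison, with 4823 genes higher and 7070 lower. Scaling from genes outside the lists gave 5207 higher and 6794 lower.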

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

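Tests of the scaling, of muscle wall, of epithelial share, of adipose tissue and of other splits of the samples were chosen after the results they measure had been seen, and those of matched genes, pseudogenes and other TOP mRNAs before.

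In groups of 4, a library was singled out by Dixon's gap-to-range rule, which chance meets in about 1 of 20 groups. This happened in 26 of the 400 groups tested, 8 for list scores and 18 for named genes, and in 0 of 4 for library totals. Among scores (mean log2 CPM centred over libraries), Eif3h-deleted replicate 2 was highest for the unfolded protein response at 0.48. Kras G12D replicate 1 was highest for p53 targets at -0.14, replicate 2 lowest for smooth muscle at -1.92 and for enteric neuron and glia at -1.44, replicate 3 lowest for the proximal small intestine at 0.87, and replicate 4 lowest for T cells at -0.96. Doubly altered replicate 2 was highest for glycolysis at 0.59, and replicate 4 lowest for the distal small intestine at -0.71. Among wild-type CPM values, Anxa10 in replicate 1 was highest at 0.077, Syt8 in replicate 2 highest at 0.0463, Slc10a2 in replicate 2 highest at 0.695, Dsg3 in replicate 3 lowest at 0 and Cyp2e1 in replicate 4 highest at 48.5. In Eif3h-deleted libraries, Slc5a12 in replicate 2 was highest at 2.28, Dclk1 in replicate 3 highest at 3.81, Rrp12 in replicate 3 lowest at 30.7, Gcg in replicate 4 highest at 3.89 and Krt20 in replicate 4 highest at 6453. In Kras G12D libraries, Abcc6 in replicate 4 was highest at 76.6, Clu in replicate 3 highest at 36.8 and Syt8 in replicate 3 highest at 1.07. In doubly altered libraries, replicate 3 was highest for Dclk1 at 3.12, Gip at 2.27 and Gsdmc2 at 0.126, and replicate 4 was lowest for Asns at 81.2 and highest for Atf5 at 91.1.

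A difference in the effect of Eif3h deletion between the Kras backgrounds was called by camera with the preset correlation for 23 of the 39 lists. It can include an effect of the recombinase, if the wild-type mice lacked it. With an estimated correlation it called 0 (5 at an unadjusted p under 0.05), the adjusted p of the 23 running from 0.102 to 0.729, and fry called 20. The median difference, Kras G12D minus wild-type background on the log2 scale, was -2.12 for goblet, -2.35 for enteroendocrine and 0.9 for tuft cell markers, and -1.78 for the proximal small intestine. It was -0.3 for the cell cycle, -0.27 for eIF3 subunits, -0.35 for other initiation factors, -0.53 for ribosome biogenesis and -0.5 for the integrated stress response. It was 0.67 for the YAP and fetal-like programme, 2.34 for MHC class II, 2.47 for Reg and antimicrobial lectins, 2.14 for cytokines and chemokines and -0.67 for NRF2 targets. Calls were lost (adjusted p in brackets) for the cell cycle without wild-type replicates 2 (0.0721) or 3 (0.114), Eif3h-deleted replicate 1 (0.0685), Kras G12D replicates 1 (0.0563) or 4 (0.0616) or doubly altered replicate 4 (0.245), and for eIF3 subunits without Eif3h-deleted replicate 2 (0.0561) or doubly altered replicate 4 (0.0536). They were lost for Reg and antimicrobial lectins without wild-type replicates 2 (0.0527) or 3 (0.0721), Eif3h-deleted replicates 1 (0.0698) or 2 (0.0837), Kras G12D replicates 1 (0.0642) or 4 (0.0894) or doubly altered replicates 2 (0.0773) or 3 (0.0639). All 3 calls were also lost with total count scaling (0.0728, 0.0877 and 0.0576) and with scaling from genes outside the lists (0.0506, 0.0934 and 0.0934). Metabolic lists had -1.04 for sterol synthesis, -0.53 for fatty acid oxidation, -0.48 for glycolysis, -0.44 for oxidative phosphorylation and -0.42 for mitochondrial transcripts. Other cell types had 2.00 for T cells and 1.25 for myeloid cells. The lists of smooth muscle (0.89) and of enteric neuron and glia (0.93) rest on few members: edgeR called 0 of 12 and 2 of 11, with 1 and 4 at an unadjusted p under 0.05. The smooth muscle call was lost without wild-type replicate 2 (adjusted p = 0.06), Eif3h-deleted replicate 4 (0.0609), Kras G12D replicate 2 (0.0858) or doubly altered replicate 4 (0.0711), and both were lost without the libraries low in smooth muscle (0.279 and 0.103). Over all alternatives their adjusted p ran from 0.00473 to 0.664 and from 0.00386 to 0.524.

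Of named genes, edgeR's test of the interaction called the following log2 differences. Lower effects on the Kras G12D background were found for Acaa2 (-1.53), Agr2 (-3.76), Aldoa (-0.71), Asns (-1.17), Atf5 (-1.37), Atoh1 (-2.84), Ccng1 (-0.82), Creb3l1 (-1.77), Dusp4 (-1.06), Eif3a (-0.59), Eif4ebp1 (-0.44), Etv4 (-3.51), Gars (-0.63), Gcg (-2.58), Gip (-3.11), Neurod1 (-2.89), Olfm4 (-4.44), Pcsk9 (-2.74), Rrp12 (-0.95), Spink4 (-2.1), Srm (-0.66) and Sst (-1.48). Higher effects were found for Anxa1 (3.57), Ascl2 (1.11), Clu (4.41), Cyp2b10 (3.93), Dio1 (1.95), Egfr (1.11), Msln (7.55), Sesn1 (0.85), Trpm5 (1.58) and Wfdc2 (6.63). For Anxa10 (-7.04), Zyg11a (-4.15) and Dsg3 (6.13) at least 1 group had under 10 counts over its 4 libraries, so the size of the fitted difference is uncertain. The calls of Anxa10 and Ascl2 were lost in several fits that leave out 1 library.

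The rise of ribosomal protein genes in both comparisons of deleted with intact Eif3h was weighed against technical explanations. Length, GC content and abundance do not account for it, because the median exceeded the highest of 1000 medians of matched genes by at least 0.91. The same value argues against scaling, since a scaling factor moves every gene of a library alike and would leave no difference from matched genes. Reads moved from pseudogenes are argued against, because summed pseudogene CPM rose too: expressed as a fall it was at most -9.64% of the genes' rise. A list of other TOP mRNAs, which share a 5' motif with ribosomal protein genes, rose in 14 of 15 cases in both comparisons with a lower median of 1.03, so a shared regulation of TOP mRNAs may contribute, as a hypothesis found and tested on the same data. The ribosome assembly and MYC list, not chosen for that motif, also rose, with medians of 1.27 without and 0.74 with Kras G12D. The test therefore does not tell regulation of TOP mRNAs from a wider rise.

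The lower smooth muscle and enteric neuron signal in Eif3h-deleted against wild-type samples was weighed next. The scores of both lists moved together within groups over 16 libraries (Pearson r = 0.95, permutation p = 0.00042, Spearman rho = 0.90, permutation p = 0.00021, and r = 0.88 without Kras G12D replicate 2 and Eif3h-deleted replicate 4), as varying amounts of muscle wall would give. Group means were removed first, so this correlation cannot decide what lowered both lists in Eif3h-deleted samples. Sampling of less muscle wall there stays open. A uniformly larger epithelial share is argued against, since the medians of 6 lists of other cell types differed by 1.56. A change of muscle or nerve with the genotype itself stays open and was not tested.

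The fall of Cyp2e1 and adipocyte genes in Kras G12D against wild-type samples was weighed last. Of 12 adipocyte genes listed after some had been seen, 8 were measured, and Cidec, Lpl and Pck1 among them are also expressed by intestine. Their median was -1.82, and -0.26 without wild-type replicates 1 and 4. Those libraries were picked for their adipocyte signal, so the smaller median follows from the choice and does not show where the signal came from. Adipose tissue in the samples stays open. An effect of Kras G12D on Cyp2e1, with a log2 fold change of -3.36 ± 1.15 without them (adjusted p = 0.0847, in a range from 0.000111 to 0.128 over 32 alternatives), stays open as well.

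Other splits of the samples were counted for each comparison. In each of the 5 pairwise comparisons, 1 of 35 splits gave as many genes, the real one. This is the smallest share that 35 splits allow, and it was not adjusted over comparisons that share libraries. The other splits mix different groups, which raises the fitted spread and can lower their counts. A cause that follows the groups would not be seen this way. The highest other split gave 0 genes for Eif3h-deleted against wild type, 15 for Kras G12D against wild type, and 0, 1136 and 219 for doubly altered against Kras G12D, Eif3h-deleted and wild type. For the interaction 2 of 100 splits gave as many genes as the real 4863, and the other gave 7463. That split turns round all 8 Eif3h labels on the Kras G12D background and keeps 6 of 8 on the wild-type background, so its contrast approaches the sum of the deletion effects on both backgrounds.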

How the results depend on the processing

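Leaving out the libraries with adipocyte transcripts (wild-type replicates 1 and 4) or with little smooth muscle (Kras G12D replicate 2 and Eif3h-deleted replicate 4), and scaling factors from genes outside the lists, were tests chosen after the data had been seen.

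Over all alternatives, values of named genes stayed on their side of the threshold in 18821 cases, lost the call in 771, gained it in 4 and reversed in 1. Called lists stayed called in 3197 cases and lost the call in 235, of which 124 came from the estimated correlation. Counts of changed genes ranged, leaving out 1 library at a time, from 10679 to 11931 for Eif3h-deleted against wild type, 3568 to 6133 for Kras G12D against wild type, 9029 to 10074, 3052 to 4911 and 11424 to 12162 for doubly altered against Kras G12D, Eif3h-deleted and wild type, and 3880 to 5575 for the interaction. In the same order, a test against 1.5-fold gave 5229, 460, 4191, 688, 6245 and 1021 genes by its stricter null. With an estimated correlation 2, 0, 0, 3, 3 and 0 lists were called. Kras G12D against wild type and the interaction gave 1641 and 3163 genes with sex as a covariate over 14 samples, and the former 1697 over those samples without it. Without the adipocyte libraries they gave 2145 and 3122. Without the libraries low in smooth muscle, doubly altered against Eif3h-deleted gave 2861 and the interaction 3222. These have fewer samples. A replicate block gave 11265, 4878, 9574, 3987, 11801 and 4374, although replicate numbers did not pair the samples: only 2 of 16 libraries correlated best with their own number. With the test against 1.5-fold, the Kras gene was not called at 0.35 in Eif3h-deleted and 0.52 in Kras G12D against wild type, 0.24 in doubly altered against Eif3h-deleted and 0.59 against wild type, nor the Eif3h gene at 0.57 in doubly altered against Eif3h-deleted. The Kras gene in doubly altered against Eif3h-deleted samples lost its call with total count scaling (0.16), with sex as a covariate (0.21) and without the low-muscle libraries (0.24), and its values leaving out 1 library ran from 0.20 to 0.25, with the call lost without Eif3h-deleted replicates 2 (0.21), 3 (0.23) or 4 (0.24) or doubly altered replicates 2 (0.20) or 3 (0.22). The Eif3h gene in Kras G12D against wild type ran from 0.15 to 0.23 leaving out 1 library at a time, was 0.08 with total count scaling, and was called, of all alternatives, only without doubly altered replicate 4 (0.23). The interaction of Ighv1-84 reversed to -0.37 without the adipocyte libraries. The cause of these changes was not tested where fewer samples or a stricter null does not give it.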

Other observations

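The test of gastric genes was chosen after the fall of a member had been seen.

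Changes not described above were found as well. Of 20 p53 targets, 13 rose and 5 fell in Eif3h-deleted against wild-type samples (median 0.72, adjusted p = 0.00434, and adjusted p = 0.406 with an estimated correlation), with Ccng1, a cyclin, going from 71.3 to 272.6 CPM and Sesn1, a sestrin that restrains mTORC1, falling from 181.8 to 23.1 CPM. Glycolysis genes rose in 8 of 18 cases and fell in 3 in doubly altered against Eif3h-deleted samples (median 0.29, adjusted p = 0.0156, and adjusted p = 0.52 with an estimated correlation). The ileal bile acid transporter Slc10a2 rose from 0.682 to 17.5 CPM between Kras G12D and doubly altered samples, although markers of the ileal end were not called as a list, with 2 higher and 5 lower of 9 (adjusted p = 0.599). Duoxa2, the maturation factor of an epithelial oxidase, rose from 12.3 to 344.1 CPM there, while the list of Reg and antimicrobial lectins had 5 higher and 4 lower of 12, or 6 and 4 adjusted over the list alone (adjusted p = 0.843).

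Several genes with large rises, such as Anxa10, Psca and Vsig1, are known from gastric epithelium, so a gastric programme raised by Eif3h deletion on the Kras G12D background was tested as a hypothesis on 9 other measured gastric genes. The rise of Anxa10 given above was on the wild-type background, and its effect of the deletion was lower with Kras G12D (-7.04, of uncertain size). Of these 33.3% were higher in doubly altered than in Kras G12D samples (Muc1, Cldn18 and Ctse) and the other 6 lower, with a median of -1.68 (adjusted p = 0.126, and adjusted p = 0.229 with an estimated correlation). The share lies between 25%, under which a programme would have been argued against, and 50%, from which it would have been supported. Over all genes, 4670 of 18348 were called higher in this comparison. The list as a whole did not rise, and on the wild-type background 0 of the 9 genes were higher and 4 lower. Several members lie under 1 CPM, so whether a part of a gastric programme rose stays open. Which of the risen genes share a regulator was not tested.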
